A study of Homo sapiens with 199 samples.

How the data were processed

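Total RNA of human skin biopsies was sequenced, and the deposited table held raw read counts per gene. Per the submitters' processing notes, the authors trimmed reads with cutadapt 2.0, aligned them to GRCh37 with Subread 1.5.0 and counted reads per gene with featureCounts. The deposited values were checked to be whole, non-negative counts of 57905 Ensembl gene identifiers in 199 libraries. The annotation behind the counts and the strand setting of the counting are not given in the sources used here. Reads of a gene and of its antisense partner therefore cannot be told apart, and counts of near-identical copies (DEFB4A and DEFB4B, the SPRR2 and LCE3 genes, KRT6A and KRT6C, HSPD1 pseudogenes) are uncertain as to which copy they came from. The reference annotation at hand was of another build, so no coordinates are given. Gene symbols came from a table of gene names, which matched 51996 of the identifiers.

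Each library was placed in 1 of 9 groups from the labels, by treatment and week. Total counts ran from 11627459 to 57549365 per library, and 1 library had a total under 0.5 times the median. No library's counts were a copy of another's in its group. Replicate numbers were given here within each group, in the order of deposit, and the labels do not link biopsies of a patient across weeks. All tests therefore treated biopsies as independent, although repeat biopsies of the same patients are among them. No sequencing or library batch is stated in the labels.

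Genes were tested with edgeR 4.0.16 (R 4.3.3) on all 199 libraries in a single model of the 9 groups, with TMM normalization and the quasi-likelihood test with Benjamini-Hochberg adjustment. The filter on low counts, filterByExpr, kept 31134 genes. A gene was called at an adjusted p below 0.05. Log2 fold changes are given with the standard error, which was computed as the size of the log2 fold change over the square root of the F value. Levels are in CPM, the count of a gene scaled to its library's total over the filtered genes after TMM normalization, with the SD over libraries. The pooled CPM of genes with few counts, described below, used library totals without this normalization. The 13 comparisons were lesional skin at baseline against healthy skin, each week of each treatment against its own baseline, the difference between the treatments in these changes as an interaction at each week, both treatments at baseline, and week 4 of each treatment against healthy skin.

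A disease score placed each library on the line from healthy to baseline lesional skin. It projected the log2 CPM (prior count 2) of a library on the baseline difference over 8207 disease genes, which were called and changed at least 2-fold between baseline and healthy skin. The healthy mean is 0 and the mean of the 2 baseline groups is 1. Of the disease genes, 3183 were higher and 5024 lower in lesions, the lower ones including the fat gene AQP7 and the immediate early genes JUN and FOSB. The score therefore does not measure inflammation alone, and a difference in handling between healthy and lesional biopsies would enter it. Recovery of a gene is the share, in percent, of its baseline difference from healthy skin that was gone at a given week. Score changes were tested by two-sided permutation with 100000 resamples, and differences between treatments by permuting treatment labels within a time point, with Benjamini-Hochberg adjustment over 9 tests.

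Lists of 10 pathways, 18 cell types or skin structures and 2 measures of RNA quality were tested by permutation of their mean log2 CPM, in the same way, with adjustment over all 390 tests of the 30 lists in 13 comparisons. Such a test asks whether a list moved and does not compare it with other genes. The smallest p that the permutations can give is 1e-05. Where the called members of a list are counted, the number called over all genes is given, followed by the number adjusted over the list alone where it differs. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used.

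Genes were named by a fixed rule. It took the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM in a compared group. It left out genes without a symbol, XIST, TSIX, Y-linked genes and antigen receptor segments. It added up to 3 members with the smallest adjusted p of each list described, with the strongest member going the other way. It also took, in every comparison, IL17A, IL17F, IL17RA, IL17RC, IL22, IL23A, IL12B and IL23R. Where fewer are printed, they were taken in the order of the rule. A few genes that the rule takes are not reported here. For genes with 3 or fewer counts over all libraries of a group, the ratio of pooled CPM is given with its 95% counting interval, or, with no counts, a bound computed from 3 counts over the group. Such intervals cover counting error only. The share of a gene's summed CPM in the highest library of the group with the higher level, and the ratio of mean CPM without that library, were added after seeing the data.

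The groups, the tests, the lists, the naming rule and most alternatives were fixed before the data were examined. These alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom (limma 3.58.1), a model of only the compared groups, removal of the library of low depth, the total count as a covariate, ixekizumab groups thinned to the guselkumab group sizes in 20 random draws, a prior count of 0.5, the median of a list in place of its mean, disease genes defined at 4-fold, and disease genes defined from the other treatment's baseline. Added after seeing the data were a fit without 17 libraries in which 3 abundant RNAs took over 10% of the counts, a fit without 7 libraries standing apart from the rest of their group, a fit without guselkumab baseline replicate 21, and the removal of each guselkumab baseline library in turn. A library stood apart when over 100 genes had a level of at least 1 CPM in it and over 4 times that of the next highest library of its group.

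The edgeR steps were tested on simulated counts made from the real means and library sizes, with 200 changed genes. In the simulated comparison of guselkumab week 4 with baseline, 79% of the genes changed 2-fold and 96% of those changed 4-fold were recovered among 25708 genes, with 6 false calls. In that of ixekizumab week 4 with baseline, these shares were 85% and 99% among 26111 genes, also with 6 false calls. The simulated genes varied independently of each other, with no libraries standing apart, in a fit of 2 groups. These counts therefore do not show how many false calls the real data give. Splits of the real guselkumab week 4 and baseline libraries called up to 363 genes in such a fit. In 1000 simulations, the permutation test called 4.5% of the comparisons of 2 groups without a difference and 84% of those with a difference of 1 SD. For the difference of changes these shares were 5.8% and 61.6%.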

Results

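Lesional skin of patients with psoriasis was biopsied before and during treatment with 1 of 2 antibodies, and total RNA of each biopsy was sequenced. Ixekizumab (80 mg, given every 2 weeks) binds the cytokine IL-17A. Guselkumab (100 mg) binds IL-23, the cytokine that maintains the T cells that make IL-17A. The ixekizumab groups held 32 biopsies at baseline, 25 at week 1, 24 at week 2 and 24 at week 4. The guselkumab groups held 22 at baseline, 14 at week 1, 16 at week 2 and 16 at week 4. Skin of healthy controls gave 26 biopsies. Total counts per library ran from 18732021 to 36309798 in healthy skin, from 11627459 to 57549365 with ixekizumab and from 17188590 to 55590063 with guselkumab. In 17 libraries 3 abundant RNAs (7SK, and ENSG00000258486 and ENSG00000265150, which the table of gene names lacks) took over 10% of the counts. Of these, 10 were ixekizumab libraries (3 at baseline, 3 at week 1, 4 at week 2), 7 were guselkumab libraries (3 at baseline, 2 at week 1, 1 at week 2, 1 at week 4) and none was of healthy skin. The data address how fast each antibody moves lesional skin toward healthy skin in the first 4 weeks, and whether the treatments differ in this.

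The disease score, which is 0 at the mean of healthy skin and 1 at the mean of lesional skin before treatment, fell at every week with ixekizumab. It changed from 1.05 ± 0.33 (SD, n = 32) at baseline to 0.795 ± 0.187 at week 1, 0.653 ± 0.207 at week 2 and 0.523 ± 0.197 at week 4. These changes were -0.251 (permutation adjusted p 0.00372, 23 of 25 libraries below the baseline mean), -0.393 (4.5e-05, 23 of 24) and -0.522 (4.5e-05, 24 of 24). With guselkumab the score was 0.954 ± 0.292 at baseline (n = 22), 0.938 ± 0.19 at week 1, 0.809 ± 0.315 at week 2 and 0.700 ± 0.313 at week 4. Of its changes, -0.0164 at week 1 (permutation adjusted p 0.857, 8 of 14 libraries below the baseline mean) and -0.145 at week 2 (0.173, 9 of 16) did not pass, and -0.255 at week 4 passed (0.03, 15 of 16). Without the 17 libraries rich in 3 abundant RNAs the week 4 change with guselkumab was of similar size (-0.254), and with fewer libraries it no longer passed (adjusted p 0.0561, range over its alternatives 0.0186 to 0.0561).

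**Figure D1:**
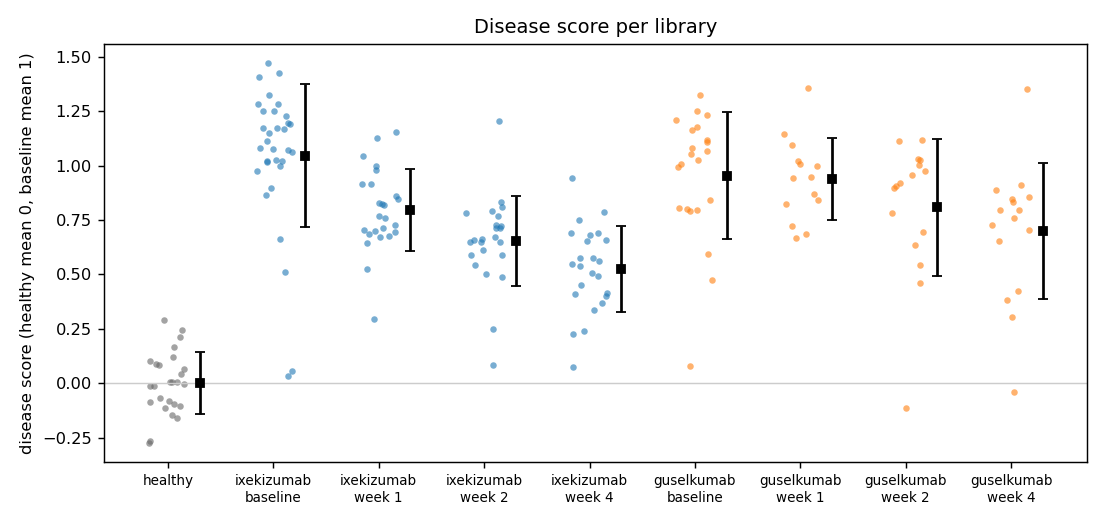
Disease score (no unit, healthy mean 0, baseline mean 1) of each library as a point, for the 9 groups on the horizontal axis, with squares and bars for the mean and SD. At week 4 the mean was 0.523 with ixekizumab and 0.700 with guselkumab.

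Lesional skin before treatment was compared with healthy skin to define the disease difference (54 against 26 libraries). The antimicrobial gene DEFB4A (ENSG00000171711) had a log2 fold change of 13.14 ± 1.12 (SE, edgeR adjusted p 7.01e-23). Its level was 356 ± 321 CPM at ixekizumab baseline, the higher of the 2 baselines, and 0.0207 ± 0.0462 CPM in healthy skin. S100A7A (ENSG00000184330), of the same function, rose by 10.85 ± 0.99, from 0.971 ± 2.56 CPM to 2210 ± 1320 and 1390 ± 976 CPM, and lay above the healthy mean in 53 of 54 libraries. The cytokine gene IL36A (ENSG00000136694) had 3 counts over all healthy libraries, and its pooled level was 9130 times as high in lesions (95% counting interval 3130 to 44300). DEFB4B (ENSG00000177257, 10.86 ± 1.24), LCE3C (ENSG00000244057, 10.11 ± 1.30), the protease inhibitor SERPINB4 (ENSG00000206073, 10.08 ± 0.92) and the cytokine IL19 (ENSG00000142224, 9.74 ± 0.94) also rose. The pseudogene HSPD1P3 (ENSG00000255128), at 0 in every healthy library, was at least 1600-fold higher in lesions. The largest falls were those of DHRS2 (ENSG00000100867, -6.47 ± 0.54), DEFB132 (ENSG00000186458, -6.06 ± 0.57), FOXN4 (ENSG00000139445, -5.90 ± 0.37), NR4A1AS (ENSG00000259884, -5.82 ± 0.40), HBD (ENSG00000223609, -5.74 ± 0.55), TRARG1 (ENSG00000184811, -5.54 ± 0.56), FOSB (ENSG00000125740, -5.46 ± 0.41) and C14orf180 (ENSG00000184601, -5.44 ± 0.56). A single healthy library held 93.8% of the summed CPM of DHRS2 in healthy skin and another held 93.3% of that of HBD, and without these the log2 ratio of mean CPM went from -6.47 to -2.52 and from -5.77 to -1.93. In all, 10555 genes were called higher and 12344 lower, and 8207 of these changed at least 2-fold.

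Genes of the IL-17 pathway were raised in lesions. IL17A (ENSG00000112115) rose by 6.40 ± 0.69, IL22 (ENSG00000127318) by 4.38 ± 0.70, IL12B (ENSG00000113302) by 4.11 ± 0.42, IL23A (ENSG00000110944) by 1.12 ± 0.15 and IL23R (ENSG00000162594) by 0.85 ± 0.32. IL17F (ENSG00000112116) had 2 counts over all healthy libraries, against which its pooled level was 268 times as high (95% counting interval 74 to 2210). The receptor genes IL17RA (ENSG00000177663, -0.17 ± 0.07, edgeR adjusted p 0.0152) and IL17RC (ENSG00000163702, -0.27 ± 0.07) were slightly lower. Of the 26 IL-17-responsive epidermal genes, 24 rose and 2 fell, also when adjusted over the list alone, and the list's mean log2 CPM was 4.96 higher (53 of 54 libraries above the healthy mean). S100A7 (8.41 ± 0.71) and IL36G (5.97 ± 0.50) rose, and CXCL2 fell by 1.46 ± 0.33 on the log2 scale. Among the IL-23 and type 17 cytokine genes 9 rose and 1 fell, with a list change of 1.48.

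Lists of the epidermis, of interferon and of immune cells were mostly higher in lesions, with a permutation adjusted p of 9.07e-05 at a p of 1e-05, the smallest the permutations can give, unless another is stated. Hyperproliferation keratins rose by 4.29 (5 of 5 genes, KRT16 5.27 ± 0.60, KRT6A 5.19 ± 0.60). The LCE3 and SPRR genes of the cornified envelope rose by 6.27 (14 of 14, SPRR2A 9.41 ± 0.84). Cell cycle genes rose by 1.71 (20 of 20, CCNB1 2.70 ± 0.23), IL-1 family genes by 2.61 (13 of 14), type I interferon genes by 2.34 (21 of 21, IFI27 4.35 ± 0.33) and interferon gamma genes by 1.5 (8 higher, 1 lower, 3 not passing). Rises were also found for T cells (0.82, CD3D 2.17 ± 0.26, with CD5 lower at -0.80), regulatory T cells (0.62, adjusted p 0.000289), resident memory T cells (0.51, 0.00187), mature dendritic cells (1.04, LAMP3 2.87), Langerhans cells (0.88, 0.00996), MHC class II genes (0.89) and melanocytes (1.23, PMEL 1.84). The rise of resident memory T cells was not called with the median of its genes (adjusted p 0.834, range over its alternatives 0.000284 to 0.834).

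Lists of fat, muscle, fibroblasts, endothelium and the sebaceous gland were lower in lesions. Adipocyte genes fell by 4.21 (9 of 9 genes, AQP7 -4.71 ± 0.39), sebaceous gland genes by 2.97 (12 of 12), muscle genes by 2.09 (7 of 7), fibroblast genes by 1.74 (9 of 10, FBLN1 -1.84), endothelial genes by 1.38 (7 of 7, CLDN5 -2.30) and erythroid genes by 2.49 (4 of 4). Immediate early genes, which respond to stress and handling within minutes, fell by 2.21 (9 of 11, JUN -2.79 ± 0.12) and were below the healthy mean in 54 of 54 libraries. Mitochondrial genes fell by 0.77 (10 of 13, MT-ND2 -1.12). No change of the list was called for late differentiation genes (0.22, adjusted p 0.798, 12 genes higher, 2 lower), neutrophils (-0.09, 0.85, 1 higher, 3 lower), macrophages (-0.28, 0.453, 1 lower, or 0 adjusted over the list alone), mast cells (0.00, 0.99, 4 higher, and 3 adjusted over the list alone), B and plasma cells (-0.22, 0.605, 5 lower), eccrine glands (-1.0, 0.142, 1 lower, or 0 adjusted over the list alone) and hair follicles (-0.83, 0.493, none of 9 genes).

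**Figure D2:**
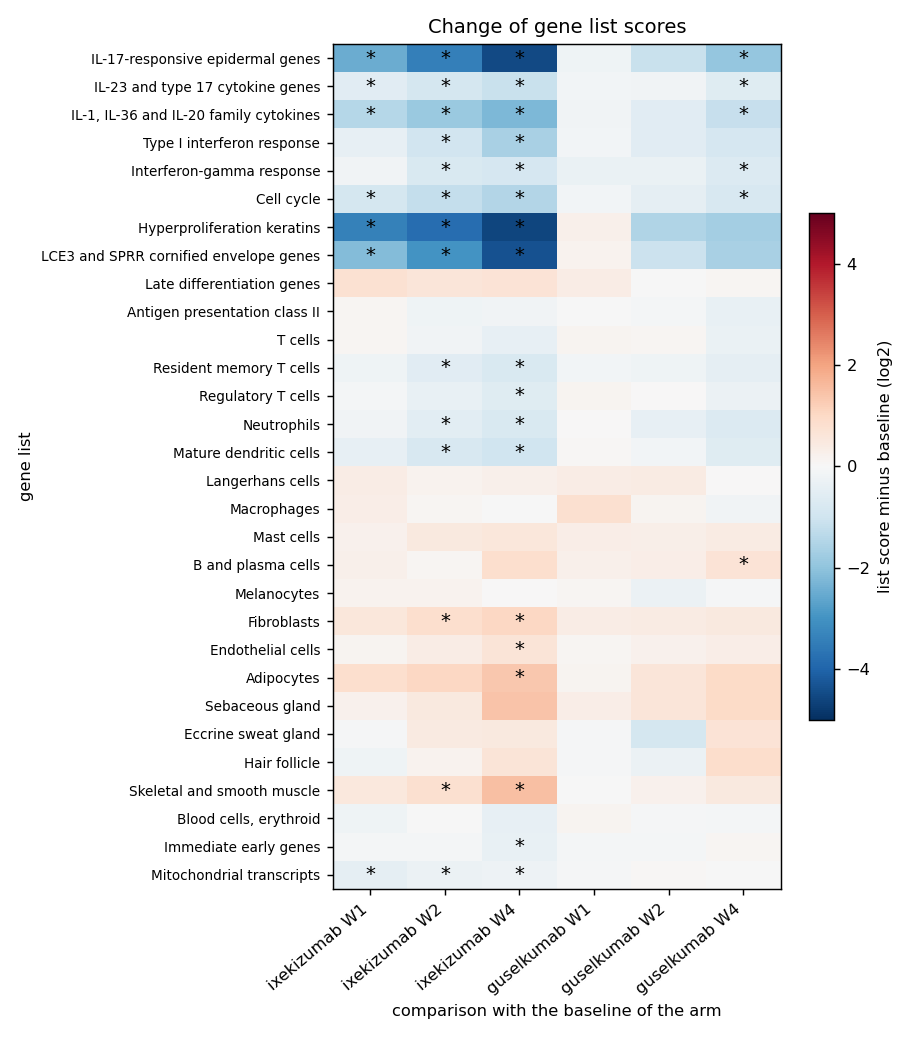
Change of mean log2 CPM of each of the 30 gene lists (vertical axis) from baseline at weeks 1, 2 and 4 of each treatment (horizontal axis), in log2 units as colour, with a star where the permutation adjusted p was below 0.05. The IL-17-responsive genes changed by -4.53 at week 4 of ixekizumab and by -1.94 at week 4 of guselkumab.

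The first comparison with treatment asked what 1 week of ixekizumab changed (25 libraries against 32 at baseline). Epidermal targets of IL-17A were already lower. IL19 fell by 6.51 ± 0.78 on the log2 scale, from 14.9 ± 20.6 to 0.171 ± 0.407 CPM, and lay below the baseline mean in 25 of 25 libraries (edgeR adjusted p 2.04e-11). The tight junction gene CLDN17 (ENSG00000156282, -5.41 ± 0.64), LCE3B (ENSG00000187238, -4.64 ± 0.73), the nitric oxide synthase NOS2 (ENSG00000007171, -4.42 ± 0.58), DEFB4A (-4.16 ± 0.70), IL36A (-4.15 ± 0.62), DEFB4B (-4.14 ± 0.79) and the pseudogene HSPD1P2 (-4.05 ± 0.54) fell in at least 23 of 25 libraries. Of the IL-17-responsive genes 24 fell and 1, CXCL5 (1.81 ± 0.60), rose, also when adjusted over the list alone, with a list change of -2.48 (permutation adjusted p 9.07e-05, 24 of 25 libraries lower). ZC3H12A, an inhibitor that IL-17A induces, fell by 1.73 ± 0.24. The rise of CXCL5 turned into a fall with limma-voom and without the libraries rich in 3 abundant RNAs. IL17A itself fell by 1.29 ± 0.44 (edgeR adjusted p 0.0181), IL17F by 1.52 ± 0.46, IL12B by 2.25 ± 0.36 and IL23A by 0.84 ± 0.16. No change was called for IL22 (-1.31 ± 0.60, adjusted p 0.0932), IL23R (0.08), IL17RA (0.06) and IL17RC (-0.01).

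Keratinocyte growth genes fell at week 1 of ixekizumab as well. The hyperproliferation keratins changed by -3.38 (5 of 5 genes, permutation adjusted p 9.07e-05, 21 of 25 libraries lower), and KRT6A went from 10700 ± 6960 to 2000 ± 3300 CPM. The LCE3 and SPRR genes changed by -2.19 (13 of 14 genes, 0.00449), IL-1 family genes by -1.44 (8 lower, or 9 adjusted over the list alone, and 2 higher, 0.000455), cell cycle genes by -0.87 (19 of 20, or 20 adjusted over the list alone, 0.00145), type 17 cytokine genes by -0.56 (4 lower, 1 higher, 0.0144) and mitochondrial genes by -0.43 (12 of 13, or 13 adjusted over the list alone, 0.000342). Interferon, fibroblast, macrophage and muscle lists did not pass, although 7 of 9 macrophage genes, or 8 adjusted over the list alone, were called higher. Of these CD163 rose by 2.0 ± 0.40, with a single library holding 51.4% of its summed CPM, and by 0.689 without the libraries rich in 3 abundant RNAs, where it was not called. In all, 3651 genes were called higher and 4780 lower, 1036 of them at least 2-fold. The largest rises were those of LINC01524 (4.83 ± 0.67), SPP1 (3.52 ± 0.76), LBP (3.50 ± 0.68), MME (3.34 ± 0.48), PTX3 (2.82 ± 0.55), WNT2 (2.72 ± 0.60), IL6 (2.68 ± 0.63) and CR1 (2.58 ± 0.51). A single week 1 library held 55.8% to 89.1% of the summed CPM of each of these 8. PTX3 and IL6 lay below the baseline mean in 19 of 25 libraries, while MME lay above it in 19 and WNT2 in 16. None of the 8 was called with limma-voom.

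At week 2 of ixekizumab, which asks how the change went on (24 libraries against 32), IL19 had fallen by 6.96 ± 0.82 on the log2 scale and the neutrophil attractant CXCL8 (ENSG00000169429) by 5.39 ± 0.91. DEFB4A reached 8.79 ± 21.8 CPM (-5.33 ± 0.75, edgeR adjusted p 1.48e-09, 24 of 24 libraries below the baseline mean). Falls of similar size were those of DEFB4B (-5.85 ± 0.89), HSPD1P3 (-5.84 ± 0.70), CLDN17 (-5.38 ± 0.65), HSPD1P2 (-5.36 ± 0.61) and NOS2 (-4.97 ± 0.61). The IL-17-responsive list changed by -3.43 (24 of 26 genes, or 25 adjusted over the list alone, permutation adjusted p 9.07e-05, 24 of 24 libraries). IL17A fell by 2.10 ± 0.47, IL17F by 1.52 ± 0.47, IL22 by 2.45 ± 0.68, IL12B by 2.60 ± 0.38 and IL23A by 0.95 ± 0.17. No change was called for IL23R (-0.41), IL17RA (-0.07) and IL17RC (0.04). The largest rises were those of KRTAP24-1 (2.89 ± 0.85), KRTAP29-1 (2.89 ± 0.68), KRTAP26-1 (2.88 ± 0.87), KRT40 (2.86 ± 0.48), PRND (2.75 ± 0.49), MT4 (2.73 ± 0.66), KRTAP19-1 (2.63 ± 0.78) and KRTAP17-1 (2.61 ± 0.84). A single week 2 library held 72.3% to 86.3% of the summed CPM of each. Only 2 of these 8 were called with limma-voom, and 2 without the libraries standing apart.

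Interferon and immune lists joined the fall at week 2. Type I interferon genes changed by -0.96 (17 of 21 genes, or 19 adjusted over the list alone, permutation adjusted p 0.00658), with RSAD2 at -2.02 ± 0.41, and interferon gamma genes by -0.75 (8 of 12, 0.00375), with WARS1 at -1.23 ± 0.17. Keratins changed by -3.82 (5 of 5, 0.000162), LCE3 and SPRR genes by -2.97 (14 of 14, 0.000342), IL-1 family genes by -1.86 (11 lower, 1 higher, or 12 and 2 adjusted over the list alone, 0.000162), cell cycle genes by -1.18 (20 of 20, 0.000229) and type 17 cytokine genes by -0.88 (6 lower, 1 higher, 0.000397). Mature dendritic cells (-0.80, 0.000511, 5 of 11 genes), resident memory T cells (-0.55, 0.00491, 4 of 8), neutrophils (-0.52, 0.0206, 4 of 11) and mitochondrial genes (-0.28, 0.00599, 8 of 13, or 9 adjusted over the list alone) also fell. Fibroblast genes (0.84, 0.0292, 2 of 10) and muscle genes (0.81, 0.0131, 2 of 7, TNNT3 2.15 ± 0.32) rose. The fibroblast rise was not called with the list median (adjusted p 0.052), nor the muscle rise without the libraries rich in 3 abundant RNAs (0.0513). Over all genes, 6701 were called higher and 6465 lower, 1886 of them at least 2-fold.

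At week 4 of ixekizumab, the last biopsy (24 libraries against 32), SPRR2C (ENSG00000229035) had fallen by 9.98 ± 0.91 on the log2 scale, from 22.8 ± 18.9 to 0.0192 CPM (edgeR adjusted p 8.03e-19). DEFB4A fell from 356 ± 321 to 0.924 ± 3.58 CPM (-8.56 ± 0.89), IL36A from 57.2 ± 47.1 to 0.133 ± 0.507 CPM (-8.64 ± 0.82) and IL19 by 9.01 ± 0.95. DEFB4B (-9.04 ± 1.10), HSPD1P3 (-8.63 ± 0.86) and SPRR2F (-8.09 ± 0.83) fell too, all of these in 24 of 24 libraries. HSPD1P2 had 3 counts over the week 4 libraries, a log2 ratio of pooled CPM of -8.84 (95% counting interval -11.12 to -7.29). IL17A fell by 3.65 ± 0.52 (24 of 24 libraries), IL17F by 3.27 ± 0.54, IL22 by 2.78 ± 0.70, IL12B by 3.35 ± 0.40 and IL23A by 1.21 ± 0.17. Of the receptors, IL17RA fell by 0.21 ± 0.08 (adjusted p 0.0139) while no change was called for IL17RC (0.00) and IL23R (-0.61, adjusted p 0.123). All 26 IL-17-responsive genes fell, with a list change of -4.53 (24 of 24 libraries), as did 20 of 20 cell cycle genes (-1.48), 5 of 5 keratins (-4.60), 14 of 14 LCE3 and SPRR genes (-4.35) and 20 of 21 type I interferon genes (-1.61), each with a permutation adjusted p of 9.07e-05. KRT6A went from 10700 ± 6960 to 286 ± 283 CPM, and MX1 fell by 2.34 ± 0.35.

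The immune and structural lists moved apart at week 4 of ixekizumab. Falls were called for IL-1 family genes (-2.26, permutation adjusted p 9.07e-05, 11 lower, 1 higher, or 12 and 2 adjusted over the list alone), type 17 cytokine genes (-1.12, 9.07e-05, 7 lower, 1 higher), mature dendritic cells (-1.01, 9.07e-05, 8 of 11, or 9 adjusted over the list alone, LAMP3 -1.78), resident memory T cells (-0.76, 9.07e-05, 5 lower, or 6 adjusted over the list alone, and 1 higher, RGS1 -1.95), interferon gamma genes (-0.84, 0.00364, 5 of 12), neutrophils (-0.74, 0.00116, 5 lower, 2 higher, CXCR2 -2.24), regulatory T cells (-0.60, 0.00214, 6 of 8, CTLA4 -1.38), immediate early genes (-0.36, 0.0406, 4 lower, 1 higher) and mitochondrial genes (-0.25, 0.0236, 7 of 13). Rises were called for muscle (1.51, 9.07e-05, 7 of 7, TNNT3 2.22 ± 0.32), endothelium (0.65, 0.00227, 6 of 7, TIE1 0.90), fibroblasts (1.05, 0.00463, 7 of 10, LUM 2.0) and adipocytes (1.36, 0.0282, 2 higher, 1 lower, or 1 and 1 adjusted over the list alone). The immediate early fall ended with RLE size factors (adjusted p 0.0568), and the mitochondrial fall without the libraries rich in 3 abundant RNAs (0.0538). T cells (-0.39, 0.0974), B and plasma cells (0.85, 0.0628) and sebaceous glands (1.44, 0.0633, 11 of 12 genes called higher, or 12 adjusted over the list alone) did not pass as lists. The largest rises were those of the collagen gene COL11A1 (3.54 ± 0.52), PRND (3.39 ± 0.50), H19 (3.03 ± 0.50), FNDC1 (3.00 ± 0.50), WNT2 (2.97 ± 0.61), MMP11 (2.96 ± 0.34, above the baseline mean in 24 of 24 libraries), SFRP4 (2.96 ± 0.66) and FCRL5 (2.82 ± 0.55), for which a single library held 45.2% to 68.5% of the summed CPM. In all, 9055 genes were called higher and 7655 lower, 3386 of them at least 2-fold, and the median log2 fold change of all genes was 0.10.

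**Figure D3:**
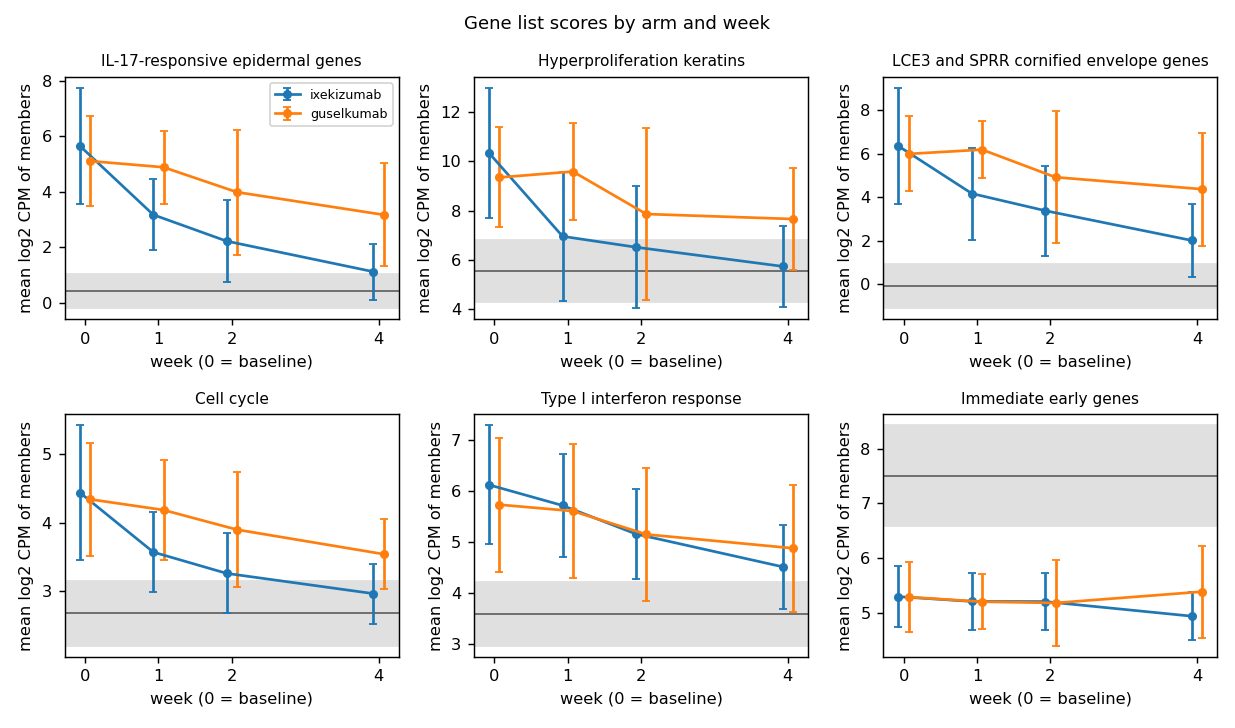
Mean log2 CPM of 6 gene lists (vertical axis, log2 CPM) against week of treatment (horizontal axis), as mean and SD over libraries, in blue for ixekizumab and orange for guselkumab, with the healthy mean and SD as a grey band. The difference between treatments in the change of the IL-17-responsive genes was -2.59 at week 4.

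The guselkumab series asked the same of blocking IL-23. At week 1 (14 libraries against 22), 1 gene was called by edgeR, with 753 at an unadjusted p under 0.05, and 5 by DESeq2 and 0 by limma-voom. It was the mitochondrial pseudogene MTCO2P12 (ENSG00000229344, -2.95 ± 0.45, edgeR adjusted p 1.3e-05), at 0.528 ± 0.31 against 4.13 ± 12.1 CPM and below the baseline mean in 10 of 14 libraries. With limma-voom its adjusted p was 1. No list passed. The IL-17-responsive genes changed by -0.22 (permutation adjusted p 0.848, 7 of 14 libraries lower, 0 of 26 genes called, and 4 lower when adjusted over the list alone), keratins by 0.24 (0.85), cell cycle genes by -0.16 (0.793), and LCE3 and SPRR genes by 0.19 (0.85). No change was called for IL23A (-0.64 ± 0.21), IL12B (-0.65 ± 0.44), IL17A (-0.46 ± 0.57), IL17F (-0.18), IL22 (-1.22), IL23R (0.00), IL17RA (0.02) and IL17RC (-0.07).

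At week 2 of guselkumab (16 libraries against 22), the cytokine gene IL1B (ENSG00000125538) was among the largest falls. It went from 57.8 ± 210 to 3.87 ± 2.76 CPM (-3.90 ± 0.66, edgeR adjusted p 0.000128, 12 of 16 libraries below the baseline mean). CXCL8 (-4.58 ± 1.06), PROK2 (-4.33 ± 0.77), TREML4 (-4.31 ± 0.82), TREM1 (-4.29 ± 0.86), OSM (-4.14 ± 0.77), FPR2 (-4.02 ± 0.81) and FCAR (-3.75 ± 0.78) fell with it. None of these 8 falls was called without the libraries rich in 3 abundant RNAs, where IL1B changed by -0.379 and TREM1 (0.073) and OSM (0.037) changed sign. None was called without guselkumab baseline replicate 21 either, and 4 genes were called in all in that fit. The largest rises were those of the fat hormone gene LEP (3.51 ± 0.88), C14orf180 (3.17 ± 0.79), H19 (2.74 ± 0.60), AQP7 (2.39 ± 0.53), SLC7A10 (1.84 ± 0.42), IGF2 (1.75 ± 0.44), CYP4Z1 (1.43 ± 0.32) and KCNIP2 (1.37 ± 0.34). In all 10 genes were called higher and 67 lower (3327 at an unadjusted p under 0.05). Limma-voom called 0 genes, and without the libraries standing apart no rise was called and 6 changed sign. A single week 2 library held 62% to 96.1% of the summed CPM of each rise. No list passed, with -1.12 for the IL-17-responsive genes (permutation adjusted p 0.211, 9 of 16 libraries lower, 2 genes lower, or 6 adjusted over the list alone), -1.49 for keratins (0.249), -0.55 for IL-1 family genes (0.437, 3 lower, or 5 adjusted over the list alone) and -0.39 for neutrophils (0.497, 2 lower, or 6 adjusted over the list alone). Neither IL23A (-0.66 ± 0.20, edgeR adjusted p 0.126) nor IL17A (-0.46, 0.826), IL17F (-0.26), IL22 (-1.27), IL12B (-0.68), IL23R (0.10), IL17RA (-0.05) or IL17RC (-0.07) was called.

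At week 4 of guselkumab (16 libraries against 22), 3 of the 8 genes followed in every comparison were lower. IL23A went from 2.26 ± 1.45 to 1.23 ± 0.38 CPM (-0.87 ± 0.20, edgeR adjusted p 0.00629, 16 of 16 libraries below the baseline mean) and IL17A from 0.732 ± 0.711 to 0.163 ± 0.246 CPM (-2.14 ± 0.61, 0.0238, 14 of 16). IL12B fell by 1.47 ± 0.44 (0.0356), and no change was called for IL17F (-1.10 ± 0.60, 0.303), IL22 (-0.92, 0.445), IL23R (-0.52), IL17RA (-0.11) and IL17RC (0.03). IL23A, IL17A and IL12B were not called with limma-voom, nor without the libraries rich in 3 abundant RNAs. The same held for all 23 called genes named for this week, of which 6 kept their call with only the compared groups. The IL-17-responsive list changed by -1.94 (permutation adjusted p 0.00725, 14 of 16 libraries lower, 8 of 26 genes, or 22 adjusted over the list alone), and IL19 by -4.06 ± 0.82. A single baseline library held 86% of the summed CPM of IL19, which changed by -1.28 without replicate 21 (edgeR adjusted p 0.297). Cell cycle genes changed by -0.80 (0.00726, 15 of 16 libraries, 17 of 20 genes, or 20 adjusted over the list alone, CCNB1 -1.28 ± 0.28). Interferon gamma genes changed by -0.70 (0.0196, 5 of 12, or 9 adjusted over the list alone, GBP5 -1.15 ± 0.33), type 17 cytokine genes by -0.61 (0.037, 4 of 10) and IL-1 family genes by -1.14 (0.0364, 6 of 14, or 8 adjusted over the list alone). B and plasma cells rose by 0.68 (permutation adjusted p 0.0263, 13 of 16 libraries above the baseline mean), with IGHG1 (3.13 ± 0.99) the only gene of the list called over all genes. The falls of type 17 cytokine and IL-1 family genes were not called without replicate 21 or without the libraries rich in 3 abundant RNAs (0.0878 and 0.0881). With the list median, neither the fall of IL-1 family genes (0.072) nor the rise of B and plasma cells (0.235) was called.

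The 8 largest falls at week 4 of guselkumab were those of the same genes as at week 2. IL1B fell to 1.54 ± 1.1 CPM (-5.23 ± 0.71, edgeR adjusted p 6.11e-08, 16 of 16 libraries) and CXCL8 fell to 1.64 ± 4.74 CPM (-6.72 ± 1.19, 15 of 16). TREML4 had 3 counts over the week 4 libraries, a log2 ratio of pooled CPM of -7.01 (95% counting interval -9.30 to -5.46). FPR2 (-5.53 ± 0.91), TREM1 (-5.44 ± 0.92), OSM (-5.02 ± 0.81), FCAR (-4.60 ± 0.84) and PROK2 (-4.44 ± 0.77) followed. A single baseline library held 49.9% to 84.5% of the summed CPM of each of the 8. Without the libraries rich in 3 abundant RNAs none was called, with IL1B at -1.768 (adjusted p 0.0772), CXCL8 at -3.202 and PROK2 at -0.598. The rises were those of KRTAP4-1 (3.07 ± 0.91), KRTAP3-2 (2.98 ± 0.80), KRTAP2-4 (2.94 ± 0.85), HSD3B1 (2.22 ± 0.64), NELL1 (2.18 ± 0.68), CHIT1 (1.71 ± 0.51), TMEM63C (1.57 ± 0.50) and GSTA3 (1.25 ± 0.40). KRTAP4-1, KRTAP2-4 and CHIT1 lay below the baseline mean in 9 of 16 libraries and KRTAP3-2 in 8, and a single library held 65% to 80.7% of the summed CPM of these 4. Keratins (-1.69, permutation adjusted p 0.0602, 0 of 5 genes), LCE3 and SPRR genes (-1.62, 0.0717, 1 of 14, or 2 adjusted over the list alone), neutrophils (-0.67, 0.0901, 5 of 11 genes lower, or 8 adjusted over the list alone), mature dendritic cells (-0.59, 0.0806, 2 of 11, or 6 adjusted over the list alone) and type I interferon genes (-0.85, 0.134, 1 of 21, or 14 adjusted over the list alone) did not pass as lists. In all, 1341 genes were called, 1190 of them lower and 359 of them at least 2-fold. The single-gene calls at this week depended on the method, since limma-voom called 0 genes (DESeq2 1585, edgeR 5932 at an unadjusted p under 0.05) and edgeR called 6 without the libraries rich in 3 abundant RNAs.

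The treatments were then compared in their changes from baseline, which tests the difference itself (values below 0 mean a larger fall with ixekizumab). The disease score differed by -0.235 at week 1 (permutation adjusted p 0.0468), -0.248 at week 2 (0.0525, not passing) and -0.268 at week 4 (0.0468). The IL-17-responsive genes differed at every week, by -2.26 at week 1 (permutation adjusted p 0.0074, 4 of 26 genes, or 21 lower and 1 higher adjusted over the list alone), -2.31 at week 2 (0.0215, 11, or 22 and 1) and -2.59 at week 4 (0.00276, 18, or 22). Keratins differed by -3.62 at week 1 (0.00449, 1 of 5 genes, or 5 adjusted over the list alone) and -2.91 at week 4 (0.0071, 5 of 5), and LCE3 and SPRR genes by -2.38 (0.0337, 2 of 14, or 8) and -2.72 (0.0204, 13, or 14), while at week 2 neither passed (-2.33, 0.122 and -1.90, 0.179). IL-1 family genes differed at week 1 (-1.28, 0.0409, 1 lower, or 5 and 1 higher adjusted over the list alone) and not at week 4 (-1.12, 0.0926). Muscle genes rose more with ixekizumab at week 4 (1.04, 0.046, 1 of 7, or 3 adjusted over the list alone). Without the libraries rich in 3 abundant RNAs, the week 1 differences of IL-1 family genes (adjusted p 0.0611) and LCE3 and SPRR genes (0.0662) and the muscle difference (0.0691) were not called. The first pair was also not called with the list median (0.0578 and 0.124), nor the muscle difference without replicate 21 (0.0612). Cell cycle genes (-0.71, 0.106 at week 1, -0.67, 0.0829 at week 4) and type I interferon genes (-0.75, 0.259 at week 4) did not pass. The week 1 difference of the score lost its call in 4 of its alternatives (adjusted p range 0.032 to 0.119), and the week 4 difference in 4 (0.0268 to 0.0653).

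Single genes with a difference at week 4 were led by SPRR2C (-8.22 ± 1.09, edgeR adjusted p 4.92e-08), DEFB4B (-7.24 ± 1.31), SPRR2F (-6.04 ± 0.97), IL36A (-5.90 ± 0.96), DEFB4A (-5.78 ± 1.01), HSPD1P3 (-5.60 ± 1.08), SPRR2A (-5.26 ± 0.95) and the elastase inhibitor PI3 (ENSG00000124102, -4.98 ± 0.88). KRT16 (-3.99 ± 0.82), KRT6A (-3.78 ± 0.81) and LCN2 (-3.97 ± 0.68) differed too. In the other direction were TREML4 (4.46 ± 1.37), MTCO2P12 (3.10 ± 0.53), the matrix protein genes COL11A1 (2.78 ± 0.81) and POSTN (2.60 ± 0.64), and the metalloproteinase gene MMP11 (2.52 ± 0.55). None of these 5 was called with limma-voom, and TREML4 differed by 0.324 without the libraries rich in 3 abundant RNAs (adjusted p 0.78). A single library held 54.2% of the summed CPM of MTCO2P12 at guselkumab baseline. At week 1 CLDN17 (-5.45 ± 0.86, 5.2e-05), DEFB4B (-4.64 ± 1.11), LCE3B (-4.59 ± 1.0), SPRR3 (-3.89 ± 0.84), DEFB4A (-3.58 ± 0.96), IL36A (-3.57 ± 0.86) and SPRR2C (-3.40 ± 0.84) led, with KRT17 at -2.75 ± 0.68. At week 2 DEFB4B (-5.11 ± 1.13), KRTAP9-9 (-4.66 ± 1.19), HSPD1P3 (-4.48 ± 0.90), IL19 (-4.19 ± 0.99), CLDN17 (-4.16 ± 0.85) and PI3 (-3.84 ± 0.86) led. The largest positive difference at weeks 1 and 2 was that of IL6 (4.41 ± 1.05 at both), which turned negative with limma-voom and without the libraries rich in 3 abundant RNAs. IL12B differed at week 2 (-1.92 ± 0.55, edgeR adjusted p 0.0395) and week 4 (-1.88 ± 0.58, 0.0407), and not at week 1 (-1.61, 0.117). Of the called genes named here, limma-voom kept 3 of 17 at week 4, 0 of 8 at week 2 and 5 of 9 at week 1. With only the compared groups, 15, 5 and 1 kept their call.

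No difference between treatments was called for the other genes of the pathway, whose values follow for weeks 1, 2 and 4. They were -0.83 ± 0.71, -1.64 ± 0.70 and -1.51 ± 0.78 for IL17A, and -1.34 ± 0.74, -1.25 ± 0.73 and -2.17 ± 0.79 for IL17F (smallest edgeR adjusted p 0.0924). For IL22 they were -0.09, -1.18 and -1.86, for IL23A -0.21, -0.29 and -0.34, and for IL23R 0.08, -0.51 and -0.09. The receptor genes gave 0.04, -0.02 and -0.11 for IL17RA and 0.06, 0.12 and -0.03 for IL17RC. Called genes numbered 42 higher and 275 lower at week 1, 71 and 582 at week 2, and 1284 at week 4, of which 1101 lower. These counts ran from 3 to 773 at week 1, from 47 to 3388 at week 2 and from 569 to 2589 at week 4 over the alternatives.

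Before treatment the 2 groups were compared to see whether they started alike (32 against 22 libraries). No list was called, with the IL-17-responsive genes at 0.54 (permutation adjusted p 0.54), type 17 cytokine genes at 0.46 (0.0931) and muscle genes at -0.68 (0.0698). Hyperproliferation keratins, also not called, had a mean log2 CPM of 10.3 ± 2.64 with ixekizumab and 9.34 ± 2.03 with guselkumab. Type 17 cytokine genes passed without replicate 21 (0.0462) and without the libraries rich in 3 abundant RNAs (0.0426), and muscle genes with the list median (0.0315). The disease score differed by 0.0914 (permutation p 0.304). Of 55 called genes, 19 were higher with ixekizumab, among them MUC19 (3.87 ± 0.66, edgeR adjusted p 0.000167, above the other group's mean in 12 of 32 libraries, with 89.2% of its summed CPM in 1 of them), KRT17P3 (1.80 ± 0.39), ALDH1A3 (1.28 ± 0.27) and ANXA1 (1.14 ± 0.27). Lower were 36, among them IL6 (-3.04 ± 0.64), MTCO2P12 (-3.02 ± 0.33), CCL17 (-2.51 ± 0.47), PROK2 (-2.44 ± 0.52), CCL13 (-2.33 ± 0.44) and CD69 (-2.03 ± 0.35). Without guselkumab baseline replicate 21, 14 genes were called, and CCL17, CCL13, IL6 and PROK2 turned to higher with ixekizumab. No other library was left out singly for this purpose, so whether others act alike was not tested. Without the libraries rich in 3 abundant RNAs more genes differed, 0.565% of the filtered genes against 0.177% in the main fit. Limma-voom called 0 genes here and DESeq2 73, with 3239 at an unadjusted p under 0.05 by edgeR. No difference was called for IL17A (1.03 ± 0.45, 0.382), IL17F (1.20, 0.314), IL22 (-1.72, 0.153), IL12B (0.85), IL23A (0.23), IL23R (0.55), IL17RA (0.06) and IL17RC (-0.01).

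Genes called at week 4 were shared between the treatments, which have no library in common. Both called 1261 genes in the same direction, 1126 of them lower, against 292.6 expected of independent lists for the lower and 43.9 for the higher genes. Of the higher and lower genes called with guselkumab, these were 89.4% and 94.6%, and 1 gene lower with guselkumab was higher with ixekizumab. With limma-voom no gene was shared, since it called none with guselkumab, and edgeR called 6 genes with guselkumab without the libraries rich in 3 abundant RNAs. The log2 fold changes of the treatments had a Pearson correlation of 0.253 at week 1, 0.508 at week 2 and 0.708 at week 4 (Spearman 0.31, 0.602 and 0.769). These correlations are across genes, which are not independent replicates.

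What still differed from healthy skin at week 4 was asked last. With ixekizumab (24 against 26 libraries) the disease score lay at 0.523 (permutation p 1e-05, the smallest these can give), and S100A7A (5.07 ± 0.80, edgeR adjusted p 3.14e-08), the collagenase MMP1 (4.97 ± 1.04), S100A7 (4.71 ± 0.62), ADAMDEC1 (4.69 ± 0.52, 24 of 24 libraries above the healthy mean), MTND1P23 (4.34 ± 0.93), LCE3A (4.23 ± 0.79), S100A8 (3.99 ± 0.61) and TDO2 (3.92 ± 0.67) were the genes most above it. MTND1P23 lay below the healthy mean in 20 of these libraries and MMP1 in 9, and a single library held 85.3% of the summed CPM of MMP1 and 80.9% of that of S100A7A. IL17A (3.27 ± 0.83) and IL12B (1.18 ± 0.49) were higher, and the pooled level of IL17F was 47 times as high (95% counting interval 12.6 to 394). However, IL17A lay above the healthy mean in only 14 of 24 libraries (0.111 ± 0.225 CPM) and IL17F in 13 (0.113 ± 0.164 CPM). No difference was called for IL23A (0.03, adjusted p 0.915), IL22 (0.73, 0.526) and IL23R (0.51), and IL17RA (-0.36) and IL17RC (-0.28) were lower. Keratins (0.19, permutation adjusted p 0.841) and cell cycle genes (0.29, 0.0926) did not differ by the test. LCE3 and SPRR genes (2.10, 12 of 14), type I interferon genes (0.92, 15 of 21, or 16 adjusted over the list alone), T cells (0.58, 8 of 13 higher) and IL-17-responsive genes (0.70, 12 higher, 4 lower, or 14 and 5 adjusted over the list alone) were higher. The IL-17-responsive difference was not called with the list median (adjusted p 0.052). The lowest genes were FOSB (-7.09 ± 0.60), NR4A1AS (-6.99 ± 0.60), DHRS2 (-6.02 ± 0.71), IL6 (-5.53 ± 0.78), NR4A1 (-5.51 ± 0.46) and HBD (-5.34 ± 0.72), of which DHRS2 and HBD each rested mostly on 1 healthy library. Called genes were 7574 higher and 7907 lower.

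With guselkumab at week 4 (16 against 26 libraries) the score lay at 0.700 (permutation p 1e-05), and DEFB4A (9.62 ± 1.10, edgeR adjusted p 1.78e-13), S100A7A (9.31 ± 0.97), LCE3C (8.72 ± 1.33), CLEC3A (8.62 ± 1.17), DEFB4B (8.49 ± 1.30), LCE3A (8.42 ± 0.88) and SERPINB4 (7.86 ± 0.87) remained far above healthy skin. IL36A was 960 times as high in pooled level (95% counting interval 328 to 4660), and IL17F 80.4 times (21.7 to 672). IL17A (3.75 ± 0.86), IL22 (4.32 ± 0.79) and IL12B (2.21 ± 0.50) were higher, although IL22 lay above the healthy mean in only 8 of 16 libraries, 1 of which held 88.7% of its summed CPM, IL23A (0.14, adjusted p 0.58) and IL23R (0.06) were not called, and IL17RA (-0.31) and IL17RC (-0.24) were lower. The IL-17-responsive genes (2.75, 20 higher, 3 lower, or 21 and 3 adjusted over the list alone), keratins (2.11, 4 of 5, KRT16 3.66 ± 0.61), LCE3 and SPRR genes (4.46, 14 of 14), cell cycle genes (0.86, 17 of 20) and type I interferon genes (1.29, 18 of 21) were higher, each with a permutation adjusted p of 0.0009 or lower. NR4A1AS (-5.78 ± 0.66), DHRS2 (-5.67 ± 0.83), DPPA2P4 (-5.32 ± 0.52), IL6 (-5.30 ± 0.92), HBD (-5.14 ± 0.85) and SULT1C3 (-5.08 ± 0.67) were the lowest. Of these DHRS2, HBD and SULT1C3 each rested mostly on 1 healthy library, which for SULT1C3 held 94.2% of its summed CPM in healthy skin. Called genes were 7787 higher and 8215 lower.

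Recovery was also counted gene by gene among the 8207 disease genes. With ixekizumab 218 genes had recovered by at least 75% at week 1, 519 at week 2 and 1337 at week 4, with a median recovery of 22.4%, 36.9% and 49.3%. With guselkumab these were 52, 91 and 205 genes, and the median was 2.1%, 16% and 27.3%. When 1000 random parts of the baseline libraries were set against the rest, with no treatment in between, the median was 73 genes with ixekizumab and 43 with guselkumab. The highest draw lay below the 218 genes of week 1 of ixekizumab. With guselkumab it lay above the 52 and 91 genes of weeks 1 and 2, and below the 205 genes of week 4. The parts held fewer libraries than the groups compared at each week, so these draws are a rough guide.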

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

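All results here are differences between the treatments in the change from baseline, each tested as an interaction or by permuting treatment labels, and of the tests that weigh explanations for them, the thinning of the groups was fixed before the data were examined and the comparison of levels at week 4 was chosen only after the results were seen. A value below 0 means a larger fall, or a smaller rise, with ixekizumab. Such differences were called for 317 genes at week 1, 653 at week 2 and 1284 at week 4. In the fit of only the compared groups the numbers were 3, 0.373% of the filtered genes and 681, and 7, 2 and 2 of 30 splits of the libraries, the real one included, reached them, so chance was not excluded for these counts by that fit. The disease score differed by -0.235 at week 1 and -0.268 at week 4, and neither was called without the libraries rich in 3 abundant RNAs (-0.191, adjusted p 0.119, and -0.274, 0.0561). The IL-17-responsive epidermal genes differed by -2.26, -2.31 and -2.59 at weeks 1, 2 and 4. The keratins of proliferating epidermis differed by -3.62 at week 1 and -2.91 at week 4. The LCE3 and SPRR genes differed by -2.38 and -2.72 at these weeks. The IL-1, IL-36 and IL-20 family differed by -1.28 at week 1, and muscle genes by 1.04 at week 4. The differences of the LCE3 and SPRR genes at week 1, of the IL-1, IL-36 and IL-20 family and of muscle genes were not called without the libraries rich in 3 abundant RNAs.

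Among single genes at week 1, CLDN17 differed by -5.45, DEFB4B by -4.64, LCE3B by -4.59, SPRR3 by -3.89, DEFB4A by -3.58, IL36A by -3.57, SPRR2C by -3.40 and KRT17 by -2.75. IL6 differed by 4.41 at week 1 and by 4.41 at week 2, and these values rest on the few libraries described with the processing. At week 2 DEFB4B differed by -5.11, KRTAP9-9 by -4.66, HSPD1P3 by -4.48, IL19 by -4.19, CLDN17 by -4.16, PI3 by -3.84 and IL12B by -1.92. At week 4 SPRR2C differed by -8.22, DEFB4B by -7.24, SPRR2F by -6.04, IL36A by -5.90, DEFB4A by -5.78, HSPD1P3 by -5.60, SPRR2A by -5.26 and PI3 by -4.98. Smaller differences at week 4 were those of KRT16 (-3.99), LCN2 (-3.97), KRT6A (-3.78) and IL12B (-1.88). Positive at week 4 were TREML4 (4.46), MTCO2P12 (3.10), the matrix protein genes COL11A1 (2.78) and POSTN (2.60), and the metalloproteinase gene MMP11 (2.52), none of them called with limma-voom. Of all genes named here, limma-voom kept the call of 3 of 17 at week 4, 0 of 8 at week 2 and 5 of 9 at week 1. The difference in TREML4 was 0.324 without the rich libraries, and a single library held 54.2% of the summed CPM of MTCO2P12 at guselkumab baseline.

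More genes changed at week 4 with ixekizumab than with guselkumab, and the groups differ in size. With the ixekizumab groups thinned to the guselkumab sizes, a median of 11567 genes was called (lowest 8946 of 20 draws) against 54 in the guselkumab fit of the same kind, which argues against group size as the only cause. For the IL-17-responsive list, a different level before treatment was argued against by the level at week 4 itself, which was lower with ixekizumab by -2.05 (permutation p 9e-05). For muscle genes it stays open, since the level at week 4 differed by 0.36 (permutation p 0.237) and that at baseline by -0.68. It stays open too for MTCO2P12 and IL6, which differed by -3.02 and -3.04 at baseline. For keratins the part of a different starting level was not tested. Their mean log2 CPM was 10.3 with ixekizumab and 9.34 with guselkumab at baseline, and 5.73 and 7.66 at week 4. A faster action of blocking IL-17A than of blocking IL-23 may account for the pattern and stays open. So do the patients' assignment to the treatments and repeat biopsies of the same patients, which the labels do not link.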

How the results depend on the processing

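The fits without libraries rich in 3 abundant RNAs, without libraries standing apart and without guselkumab baseline replicate 21 were chosen after seeing the data, as was the removal of each guselkumab baseline library in turn. No paired analysis was possible because the labels do not link biopsies to patients. Where a value moved and no reason is given, the cause was not tested. Numbers of called genes are given here as percent of the 31134 genes kept by the filter, so that 1 gene is 0.00321%.

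Lesional against healthy skin, all weeks of ixekizumab and both week 4 comparisons with healthy skin kept their numbers of called genes within 1.5 times under all alternatives but 1. The exception was the thinning of the ixekizumab groups to the guselkumab sizes, which by its construction uses fewer samples. It gave a median of 14.1% in place of 27.1% at week 1 and 26.2% in place of 42.3% at week 2. In numbers of genes, its 20 draws ran widely, from 576 to 8077 at week 1 and from 4791 to 11386 at week 2. Of the 390 list tests, 388 stayed on their side of the threshold with RLE size factors, 390 with a prior count of 0.5, 390 without the library of low depth, 370 with the list median, 371 without the libraries rich in these RNAs, 381 without those standing apart and 383 without replicate 21, and no called list changed direction. Of the list tests that moved, 7 lost their call without the rich libraries, 4 without those standing apart and 3 without replicate 21. Calls of the main fit that ended without replicate 21 and also without the rich libraries were the week 4 falls of type 17 cytokine genes and of IL-1 family genes with guselkumab, and the week 4 difference of muscle genes.

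Calls of single genes with guselkumab, and of differences between treatments, moved most. At week 1 of guselkumab (0.00321%), 0.0161% were called with no filter and with DESeq2, 0.00642% without the rich libraries, and 0 genes with limma-voom and with only the compared groups. At week 2 (0.247%), they were 0.559% with DESeq2, 0.0193% without the rich libraries, 0.00642% without those standing apart, 0.0128% without replicate 21, and 0 genes with limma-voom and with only the compared groups. Without a filter, the share of higher calls at week 2 went from 13% to 27.5%. At week 4 (4.31%), they were 2.66% with no filter, 2.68% without the libraries standing apart, 2.16% without replicate 21, 0.173% with only the compared groups, 0.0193% without the rich libraries and 0 genes with limma-voom. In that fit of only the compared groups, which called 54 genes at week 4, leaving out guselkumab baseline replicate 5 gave 57 genes and leaving out replicate 4, 8, 9 or 12 gave 303, 231, 344 or 228. Leaving out replicate 1 or 15 also gave more than 57, and leaving out any of the other 15 gave 0, while the fits of weeks 1 and 2 gave 0 throughout.

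The difference between treatments at week 1 (1.02%) was 0.601% with no filter, 0.357% with limma-voom, 0.00964% with only the compared groups, 2.25% without the rich libraries, 2.48% without those standing apart and 1.98% with DESeq2. At week 2 (2.10%) it was 1.37% with no filter, 0.151% with limma-voom, 0.373% with only the compared groups, 1.25% without the library of low depth, 10.9% without the rich libraries and 1.26% without those standing apart. At week 4 (4.12%) it was 1.83% with limma-voom, 2.19% with only the compared groups and 8.32% without the rich libraries. At baseline (0.177%), the treatments differed in 0.315% with no filter, 0.565% without the rich libraries, 0.0514% without those standing apart, 0.045% without replicate 21, 0.00321% with only the compared groups and 0 genes with limma-voom. The overlap at week 4 was 0 with limma-voom, since it called no gene with guselkumab.

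The week 4 score change with guselkumab became -0.254 without the rich libraries (permutation adjusted p 0.0561, range 0.0186 to 0.0561). The week 1 score difference became -0.217 with the other treatment's disease genes (0.0697), -0.191 without the rich libraries (0.119), -0.218 without those standing apart (0.0647) and -0.221 without replicate 21 (0.0682), in a range of 0.032 to 0.119. The week 2 difference passed without the libraries standing apart (-0.271, adjusted p 0.0321, range 0.0321 to 0.117). The week 4 difference became -0.251 with the other treatment's genes (0.0653), -0.274 without the rich libraries (0.0561), -0.259 without those standing apart (0.0503) and -0.257 without replicate 21 (0.0617), in a range of 0.0268 to 0.0653. With disease genes defined at 4-fold, which leaves 1899 genes, the number recovered by 75% was smaller by construction and its share was 2.7%, 5.7% and 15.8% with ixekizumab and 0.5%, 0.9% and 2.5% with guselkumab. At week 1 of guselkumab it was 1.0% without the rich libraries.

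Changes of direction concerned single genes. With limma-voom, at week 1 of ixekizumab PTX3 became -0.27, IL6 -0.97 and CXCL5 -1.30, at week 2 KRTAP24-1 -0.26, and at week 2 of guselkumab LEP -0.002. Without the rich libraries, IL6 became -0.60 and CXCL5 -1.76 at week 1 of ixekizumab, and TREM1 0.073 and OSM 0.037 at week 2 of guselkumab. Without those standing apart, IL6 became -0.42 at week 1 and KRTAP17-1 -0.017 at week 2 of ixekizumab, and LEP -1.31, C14orf180 -0.77, IGF2 -0.18, AQP7 -0.052, CYP4Z1 -0.047 and KCNIP2 -0.001 at week 2 of guselkumab. The difference in IL6 became -2.01 at week 1 and -0.20 at week 2 with limma-voom, -2.33 and -0.091 without the rich libraries, and -2.23 at week 1 without those standing apart. At baseline, limma-voom gave IL6 0.87, CCL17 0.38, CD69 0.17 and PROK2 0.56. The rich libraries left out, these were 1.13, 0.59, 0.55 and 1.95. Without those standing apart, IL6 was 0.51, CCL17 0.35, CCL13 0.035 and PROK2 0.25, and without replicate 21 they were 0.52, 0.35, 0.039 and 0.25. DESeq2 gave CCL17 0.36.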

Other observations

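The tests of explanations in this part, the regroupings included, were chosen only after the results were seen, and the regroupings refitted with edgeR after those by limma-trend. With ixekizumab the IL-17-responsive genes had covered 47.4% of the way to healthy skin at week 1, 65.5% at week 2 and 86.6% at week 4, and with guselkumab 4.74%, 23.9% and 41.3%. Of the baseline libraries, 2 of the ixekizumab and 1 of the guselkumab group had a disease score under 0.3, closer to healthy than to other lesional skin.

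Immediate early genes such as JUN and FOSB were lower in lesional than in healthy skin at every week. The scaling of the counts was argued against as the cause, since a factor per library moves every gene alike and the list difference was -1.97 (permutation p 1e-05) after the median gene of each library was subtracted. A level that follows the disease score was argued against too. At ixekizumab week 4 the list had gone -16.2% of the way to healthy skin (95% bootstrap interval -29.9 to -3.7, 10000 draws) while the disease score fell. The score was still 0.523 at that week, so a trait of the lesion that recovers later or persists stays open. The highest mean of the 8 lesional groups was 5.38 log2 CPM, against 7.5 ± 0.92 in healthy skin. Handling or batch of the healthy biopsies and their health cannot be told apart, because all healthy biopsies form a single group and the labels give neither handling nor batch.

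The genes called at week 4 of guselkumab were mostly lower than at baseline, with IL1B and CXCL8 among the largest falls. Libraries rich in 3 abundant RNAs may hold much of this, since 6 genes were called without them, although fewer samples also lower a count. Replicate 21 of the guselkumab baseline was argued against as the only cause, since 672 genes were called without it, although in the fit of only the compared groups 0 genes were called without it, as without 14 other baseline libraries. An effect of the treatment on the IL-17-responsive epidermal genes may hold as well, since without the rich libraries their list still changed by -1.73 (permutation adjusted p 0.0292). Both stay open.

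Other splits of the same libraries into groups of the same sizes were counted for each comparison. By limma-trend, only the real one of 100 splits, which is 1, called as many genes for lesional against healthy skin (22823 genes, highest other 3), ixekizumab at week 1 (7227, highest other 2707), week 2 (12784, highest other 4750) and week 4 (17774, highest other 1), and week 4 of ixekizumab (16835, highest other 1) and guselkumab (16526, highest other 0) against healthy skin. Chance can be excluded for these if biopsies are taken as independent. For guselkumab at weeks 1, 2 and 4, the differences at weeks 1 and 2 and the baseline comparison, limma-trend called 0 genes with the real groups, so that all 100 splits gave as many, and 39 for the difference at week 4, reached by 2 of 100 (highest other 1653). Refitted with edgeR on the compared groups alone, guselkumab at week 4 gave 54 genes, reached by 2 of 50 splits (highest other 363), and the difference at week 4 gave 681, reached by 2 of 30 (highest other 4284). For guselkumab at week 4 the limma-trend count of 0 decides nothing. Few splits reached the edgeR count there, but that count fell to 0 when any 1 of 15 baseline libraries was left out. For the difference at week 4 the fits disagree, since 2 of 100 splits reached the count by limma-trend and 2 of 30 by edgeR. Chance therefore stays open for both. For guselkumab at week 1 (0 genes, 50 of 50 splits, highest other 28) and week 2 (0, 50 of 50, 221) every split reaches a count of 0, so the splits decide nothing. Chance cannot be excluded for the differences at week 1 (3, 7 of 30, 868) and week 2 (0.373% of the filtered genes, 2 of 30, 569), and the groups at baseline (1, 22 of 40, 889). Splits that called several times the real count point to a structure of the samples other than the groups, the source of which was not tested.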
